A study of Homo sapiens with 10 samples.

How the data were processed

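Total RNA of 5 human embryonic stem cell lines, each grown with 20 ng per ml FGF2 or with FGF2 withdrawn, was labelled with Cy3 and hybridised to NimbleGen expression arrays, 1 array per line and condition (10 arrays). Groups were taken from the treatment labels and pairs from the cell line labels. Each array held 388502 probes, of which 7500 were random control probes and 381002 belonged to 47633 targets, nearly all with 8 probes.

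The authors deposited an unnormalized file per array with the linear intensity of each probe. Per the file headers, images were read with NimbleScan 2.4.31 for 8 arrays and 2.4.27 for both H9 arrays, on a design for HG18. The authors also deposited a normalized intensity per probe, made with RMA per the submitters' processing notes; its values have nearly one distribution over the 8 arrays and another over the 2 H9 arrays, and its rank order on each array was that of the unnormalized file. The value table of the series holds the same normalized intensities, on a linear scale, with a largest difference of 0. A linear intensity has no fixed unit, so only differences between arrays of one target were used. No batch other than this split into 8 and 2 arrays was used, and it coincides with the H9 line; it cancels in the difference within a line unless it compressed or stretched the values.

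The unnormalized intensities were background corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, quantile normalized over the 10 arrays, put on the log2 scale and summarised per target by median polish. The offset understates the fold change of dim genes. Targets were named by RefSeq accession (19134) or by the gene ID that the files link to them (8131), with symbols from a RefSeq gene table on GRCh38.p14 used for names only; 20368 targets without a name were left out. No coordinates are given because the array design and that table use different assemblies. Of 19647 genes, 5008 had several targets and the target with the highest mean over the 10 arrays stood for the gene. Among 144 named genes, 33 had several targets and in 0 of them did another target move the opposite way by over 2-fold. XIST, its antisense gene and genes on Y were removed before any fit (32 genes), leaving 19615. Probes of recently copied genes or pseudogenes can share signal.

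The difference without minus with FGF2 was tested with limma (lmFit and eBayes) with the cell line as a block, and adjusted by Benjamini-Hochberg at 0.05. The design text says that the lines were grown in parallel in both conditions, which makes the line the pairing. Deviations from the group means correlated between -0.02 and 0.26 within a line, with a mean of 0.07, against -0.02 between lines. Gene lists (20 lists, fixed before the data were examined, with TDGF1 under its current symbol CRIPTO) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, which does not compare a list with other genes. ZNRF3 and ERVW1 were not among the genes used here. List medians per line were tested with an exact sign-flip permutation test, whose smallest two-sided p is 0.0625 for 5 lines and 0.125 for 4. A gene not above the 95th percentile of random probes on any array of a group was called not well above background there. Where the dimmer group was not above it on every array, the fold is given as a bound, "at least N-fold": the mean of the brighter group against the mean of the higher of that percentile and the gene's own value on each array of the other. Log2 differences of such genes are the fitted values and rest on that background; the bound was extended from genes below the percentile on all arrays of a group to those below it on some after the values had been seen.

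Named genes followed a rule fixed at the same stage as the lists: of the genes past the threshold with the same sign in all lines, the 12 largest rises and 12 largest falls, filled to 10 per direction by smallest p where fewer passed; 16 genes chosen in advance; and up to 4 members of each list with the smallest p. The text gives the list members that carry the comparison. The test within the run of 8 arrays and without each line in turn was planned. Reporting that run as a set of its own, the repeat of the rule on it, the test of each line against the others and the tests that set CM7 and CM14 against H7 and H14 were chosen after the responses of the lines had been seen. Alternatives fixed before the data were examined changed the background correction, normalization, probe summary, choice of target, filter on dim genes, variance model, array weights, block and threshold. Counts of alternatives include repeats. The run of 8 arrays is the fit without H9, and the value table holds the authors' normalized values. For camera, no block and a random block give the same result.

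The fit was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by 3 among 19615 genes. With 5 lines, 34% and 93% were recovered and 9 unchanged genes were called. With 4 lines, 23% and 92% were recovered and 5 unchanged genes were called. The simulated change was equal in every line, so these shares do not cover a change that 1 line does not share.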

Results

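Expression was measured in 5 human embryonic stem cell lines, CM7, CM14, H7, H9 and H14, each grown in parallel with and without fibroblast growth factor 2 (FGF2), the growth factor routinely added to keep such cells undifferentiated. The cells grew in a defined medium on Matrigel. The FGF2-grown cultures received 20 ng per ml, and in the FGF2-withdrawn cultures, at 0 ng per ml, the factor was taken away on the day after plating. The length of the culture without FGF2 is not given in the sources used here. Each line contributed 1 single-colour array per condition, so each group held 5 arrays and the cell line paired them. Nothing in the labels states further separate cultures within a line, and p-values measure the spread between lines. The median probe intensity lay between 1.90 and 4.45 times that of the random control probes of the same array, lowest in the FGF2-grown H14 array. Between 67.6% and 74.1% of probes exceeded the 95th percentile of the random probes, lowest on the FGF2-withdrawn and highest on the FGF2-grown H9 array. The 2 H9 arrays were read with another version of the scanner software than the other 8 and the authors' normalized values have another distribution in them, so results are given over all 5 lines and over the run of 8 arrays of CM7, CM14, H7 and H14. The number of arrays limits the precision.

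The first question was what the cells expressed once FGF2 was gone. In CM7, CM14, H7 and H14, POU5F1, NANOG and most other pluripotency genes measured were far lower and 8 of 29 neuroectoderm markers were higher, while the H9 cultures differed little between the conditions. POU5F1, the transcription factor OCT4 of the pluripotency network, had a normalized log2 intensity of 15.46 ± 0.10 with FGF2 and 9.70 ± 0.19 without it (SD, n = 4 lines), 54.4-fold lower (adjusted p = 0.00018, limma with cell line as a block). In H9 the log2 difference in POU5F1 was -0.57. NANOG, its partner in the network, fell by 4.40 on the log2 scale over the 4 lines (SE 0.23, adjusted p = 0.000616), at least 17.5-fold lower, against a difference of 0.67 in H9. SOX2, shared by pluripotent and neural progenitor cells, did not pass in either set of lines. Its difference was 0.20 (SE 0.21, adjusted p = 0.547) over 4 lines and 0.20 (SE 0.18, adjusted p = 0.484) over 5.

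**Figure D1:**
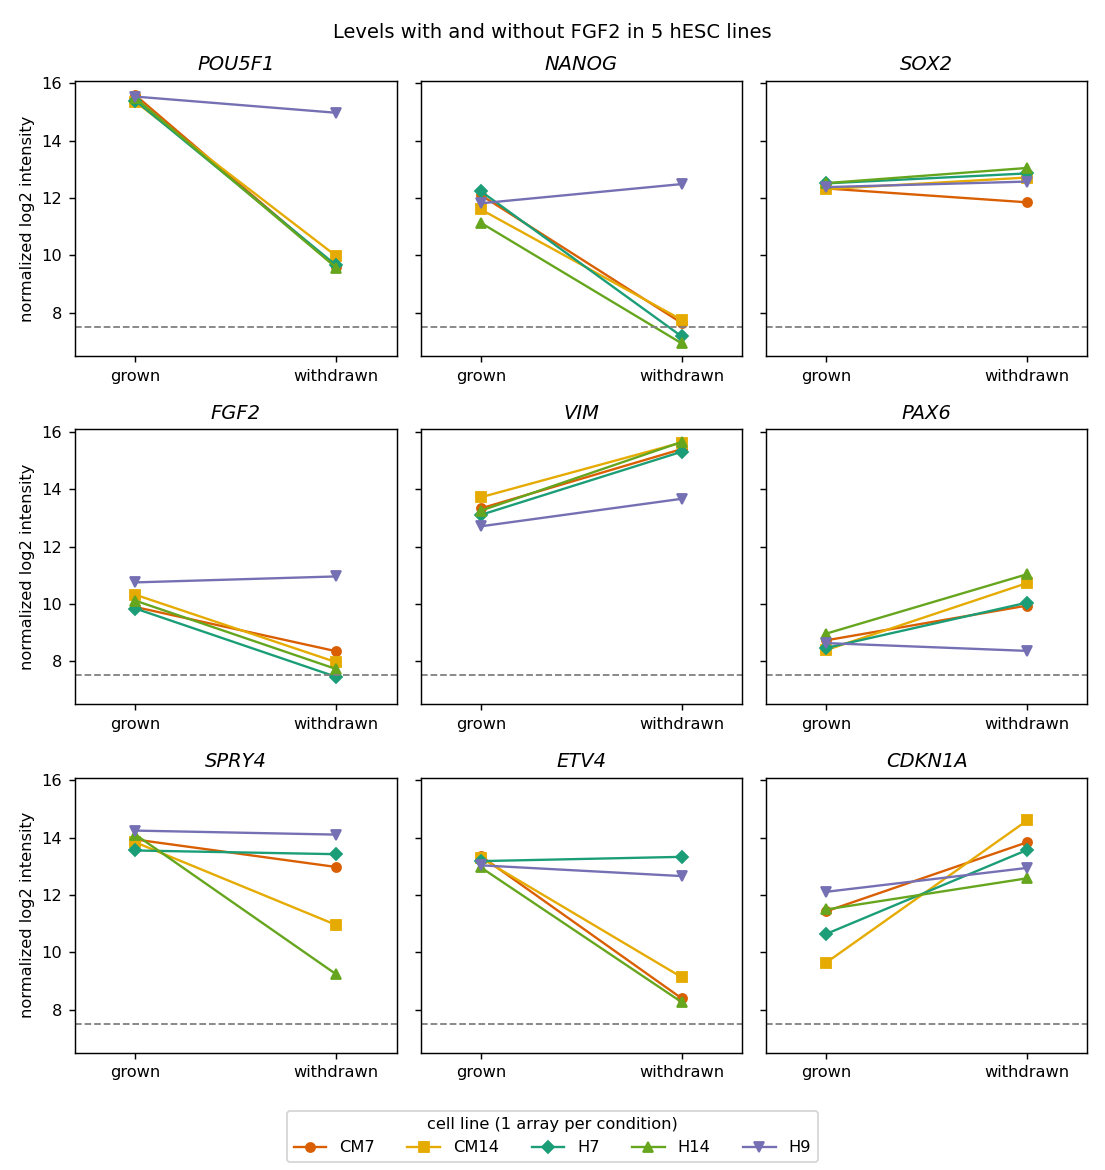
Normalized log2 intensity of 9 genes (vertical axis) on the FGF2-grown and FGF2-withdrawn array of each cell line; each line joins the 2 arrays of 1 cell line and the dashed line is the mean 95th percentile of random control probes, 7.51. POU5F1 and NANOG were lower without FGF2 in CM7, CM14, H7 and H14, and in H9 they differed by -0.57 and 0.67.

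Over all 5 lines, 0 of 19615 genes passed an adjusted p of 0.05 in limma with the cell line as a block. The smallest adjusted p was 0.0635, shared by 1011 genes. At an unadjusted p under 0.05 there were 6019 genes, 2269 higher and 3750 lower without FGF2, and 3464 genes had an adjusted p under 0.1. This count rested on the H9 pair: without it, which is also the test within the run of 8 arrays, 4426 genes changed, 1712 higher and 2714 lower. Of these, 297 rose and 686 fell by more than 4-fold. The count over 5 lines also rested on the model, with 2283 genes when the cell line was not a block. Scaling the arrays by their medians in place of quantile normalization gave 2746 genes over 5 lines, and over 4 lines it moved the share of higher calls from 38.7% to 26.6%.

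The H9 differences did not follow those of the other lines. Of the 4426 genes, 2234 had the same sign in H9, 50.5%. The median H9 difference was -0.13 for the genes that rose in the other lines and -0.08 for those that fell, where the medians over the 4 lines were 1.17 and -1.22. The SD of the log2 differences across genes was 0.42 in H9, 1.01 in H7, 1.12 in H14, 1.20 in CM7 and 1.28 in CM14.

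By the rule fixed for named genes, the 10 genes of smallest p with the same sign in all 5 lines are given in each direction, none of which passed the test over 5 lines (adjusted p = 0.0635 for each, limma). On the higher side they were VIM, POU3F3, CRYBA1, FAM181A, ZNF780B, TTC36, SPCS3, LHFPL6, LOC286297 and TUBA1A. VIM, the intermediate filament vimentin of neural progenitor and mesenchymal cells, differed by 1.91 (SE 0.23, n = 5 lines), and by 0.96 in H9 alone. POU3F3, a neural POU transcription factor, differed by 1.54 (SE 0.19) and by 1.20 in H9. LHFPL6 had the largest difference of these, 2.75 (SE 0.40), and TUBA1A, an alpha tubulin abundant in neurons, had 1.58 (SE 0.23). On the lower side they were PTPN5, ANKRD35, ACP5, EIF4E1B, HMCN1, PTGES, LPCAT1, ECHDC2, EFEMP1 and FRAT1. The phosphatase gene PTPN5 differed by -2.50 (SE 0.20), at least 3.80-fold with the withdrawn arrays held at background, and by -1.79 in H9. EIF4E1B, related to the translation factor eIF4E, differed by -2.45 (SE 0.22). ACP5 and PTGES, which encodes a prostaglandin E synthase, were above the random probes on 5 of 5 arrays with FGF2 and on 0 of 5 without it, at least 1.78-fold and 2.01-fold lower.

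The same rule was repeated over the run of 8 arrays. The 12 largest falls were in L1TD1, CYP2S1, GAL, CLDN6, AP1M2, CRIPTO, EPCAM, CDH1, DMKN, CNMD, VRTN and OTX2. L1TD1, an RNA-binding protein gene of pluripotent cells, was not well above background on any of the 4 withdrawn arrays and was at least 110-fold lower (adjusted p = 0.000217, limma). CRIPTO, the Nodal co-receptor also known as TDGF1, was 87.2-fold lower (adjusted p = 0.000167). Genes of epithelial junctions were among these falls: CDH1 (E-cadherin) was at least 54.1-fold lower, EPCAM at least 78.9-fold lower and the claudin CLDN6 103-fold lower. AP1M2, an adaptor subunit of epithelial sorting, was at least 71.4-fold lower, and the head organizer and early neural factor OTX2 at least 34.8-fold lower. For CLDN6 the differences of the 4 lines lay between -6.71 and -6.65, with -0.24 in H9.

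The 12 largest rises over the same arrays were in A2M, RFX4, NR2F1, MEIS2, SMOC1, MAP6, GRIA1, ZEB1, MEIS1, TGFB2, WLS and ZEB2. The protease inhibitor gene A2M reached 15.22 ± 0.10 from 8.27 ± 0.32 (SD, n = 4 lines), 124-fold higher (adjusted p = 0.000167, limma). RFX4, a transcription factor of the neural tube, was not well above background on any grown array and was at least 74.2-fold higher. NR2F1, an orphan nuclear receptor of the developing brain, was at least 49.6-fold higher, and the homeobox genes MEIS2 and MEIS1 were 49.5-fold and at least 30.7-fold higher. ZEB1 and ZEB2, repressors of E-cadherin, were at least 19.0-fold and 16.3-fold higher. Neuronal genes among the 12 included MAP6, a microtubule-stabilizing protein gene, at 42.1-fold, and the glutamate receptor subunit GRIA1 at 36.9-fold. In H9 the differences of the 24 genes lay between -1.71 for WLS and 0.66 for SMOC1, with VRTN at -0.87 and NR2F1 at 0.57.

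**Figure D2:**
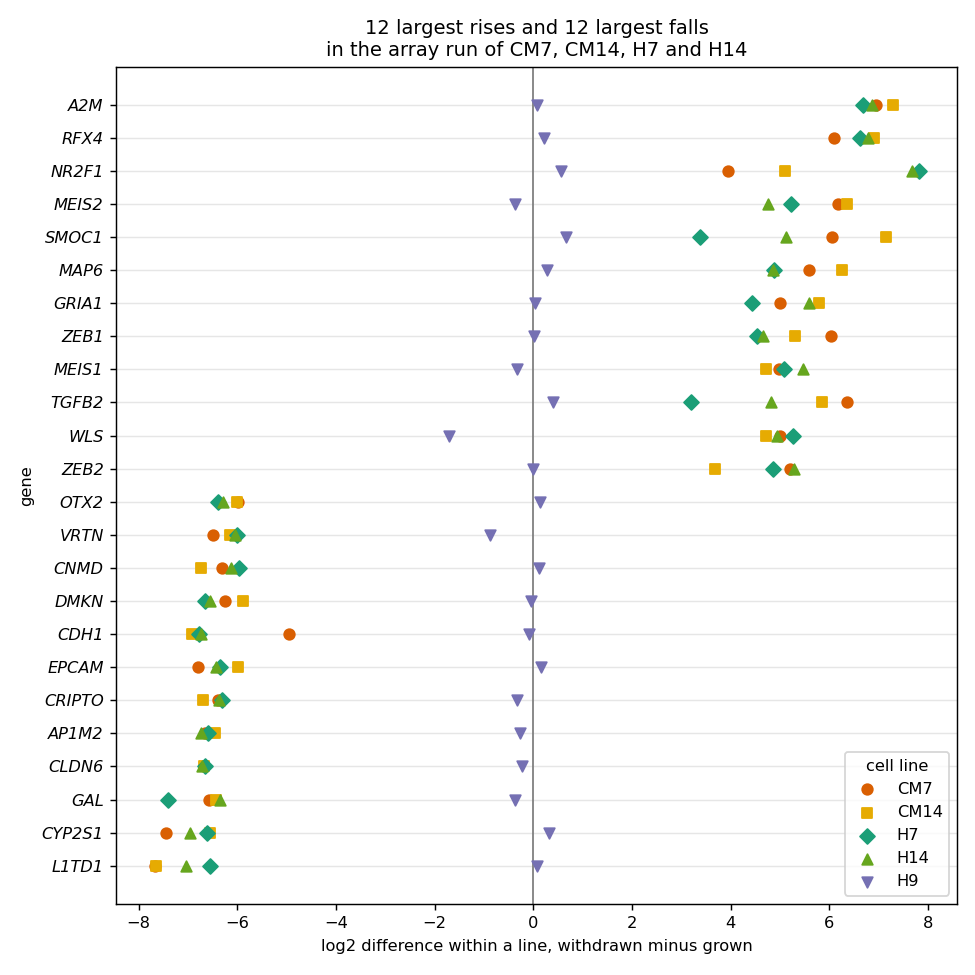
Log2 difference without minus with FGF2 (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall over CM7, CM14, H7 and H14, with 1 point per cell line. The H9 points, which took no part in the choice, lie between -1.71 for WLS and 0.66 for SMOC1.

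The pluripotency list had 26 members measured. Over 5 lines its median difference was -3.08 and the list shifted down (adjusted p = 1.14e-09, camera with a preset correlation of 0.01; adjusted p = 0.782 with an estimated correlation). No member passed over all genes tested, and 23 fell when p was adjusted over the list alone. With fry, none of the 4 lists that passed camera over 5 lines passed over the same lines. Over 4 lines fry gave the pluripotency and Nodal-activin lists an adjusted p of 0.00019 each. It also passed the trophoblast (0.00101) and endoderm (0.0171) lists, and did not pass the neuroectoderm (0.0692) and cell cycle (0.284) lists. Without H9, 20 members of the pluripotency list fell over all genes, 0 rose and 6 did not pass, and 23 fell when adjusted over the list alone. GAL, which encodes galanin, was at least 66.6-fold lower there, and FOXH1, a partner of Nodal signalling, fell as well. ZSCAN10 and UTF1 had differences of the same sign in H9, -0.74 and -0.41. The list median was negative in 5 of 5 lines, between -4.67 in CM7 and -0.02 in H9, a test in which 5 lines cannot reach 0.05 (two-sided exact sign-flip). POU5F1, NANOG and CRIPTO have processed pseudogenes of similar sequence, and their probes may share signal with them.

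Nodal-activin targets shifted down over 5 lines, with a median of -1.54 over 14 genes (adjusted p = 0.00502, camera; adjusted p = 0.782 with an estimated correlation). Over 5 lines 7 fell when adjusted over the list alone. Without H9, 9 of 14 fell over all genes and 10 when adjusted over the list alone. LEFTY1, a secreted Nodal antagonist that Nodal itself induces, was at least 49.6-fold lower there and NODAL at least 12.2-fold lower (adjusted p = 0.000226 and 0.00207, limma). Their H9 differences were 1.28 and 0.81. The H9 median of the list was 0.29, against values between -2.14 and -1.54 in the other lines.

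Neuroectoderm markers shifted up over 5 lines (adjusted p = 0.00175, camera; adjusted p = 0.782 with an estimated correlation). The median difference was 0.41 over 29 genes and was positive in 5 of 5 lines, although between 0.04 in CM7 and 0.88 in H14. In H9 it was 0.09, above that of CM7, so the shared sign says little. On average 18 of the 29 genes were above the random probes. Over 5 lines 10 rose and 1 fell when adjusted over the list alone. Within the run of 8 arrays 8 rose, 1 fell and 20 did not pass, with the same counts when adjusted over the list alone. POU3F2, the neural POU factor BRN2, was at least 15.6-fold higher and SOX1, a definitive neuroectoderm factor, at least 6.02-fold higher (adjusted p = 0.000593 and 0.00561, limma). PAX6, a factor of the early neural plate and eye, was 3.49-fold higher (adjusted p = 0.00672), and differed by -0.27 in H9. OTX2 was the member that fell. CDH2, the N-cadherin of neural epithelium, had a 5-line difference of 1.90 that did not pass (SE 0.40, adjusted p = 0.0635), as no gene did over 5 lines. Its difference was 1.65 in CM7, 2.23 in CM14, 2.02 in H7 and 3.28 in H14, against 0.31 in H9.

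Markers of other cell types gave no list shift over 5 lines in the reported fit with camera. However, the endoderm list passed under 13 of 19 alternatives and the trophoblast list under 3 (adjusted p from 0.047 to 0.392). Both counts include repeats, since leaving out H9 gives the run of 8 arrays. The endoderm count also holds the authors' values from both sources, and the 2 block alternatives, which camera does not tell apart. In the reported fit, trophoblast markers had an adjusted p of 0.233 and endoderm markers of 0.0557 (camera). Within the run of 8 arrays both lists passed downward, at 0.047 and 0.0117, and neither did with an estimated correlation (adjusted p = 0.479 and 0.806). The trophoblast call held under 11 of 17 alternatives (adjusted p from 0.0127 to 0.0897) and was lost without CM14 (0.0897), H7 (0.0697) or H14 (0.0523), with no background correction (0.0604) and with no block or a random block (0.0621 each). The endoderm call held under 16 of 17 (from 0.00108) and was lost without H7 (0.0573). Over 5 lines the adjusted p of the endoderm list lay between 0.0117 and 0.208 over the 19 alternatives, and leaving out H9 (0.0117) or H14 (0.0152) gave a call. Most of these markers were dim, with 7 of 21 trophoblast and 8 of 20 endoderm genes above the random probes on average. The trophoblast members that fell in that run numbered 6, with none rising. Adjusted over the list alone, 1 rose and 5 fell over 5 lines, and 1 rose and 7 fell over 4. The 6 included the keratins KRT18 and KRT8, 19.4-fold and 15.3-fold lower, which simple epithelia and pluripotent cells also express, and TFAP2C, at least 10.2-fold lower. CDX2, a trophectoderm factor, was above the random probes on 0 of 10 arrays. Of the endoderm list 4 genes fell and 0 rose, with 3 falls over 5 lines and 6 over 4 when adjusted over the list alone. FOXA3 was at least 16.2-fold lower and KRT19 at least 12.7-fold lower, and the endoderm factors SOX17 and GATA6 did not pass over 5 lines (adjusted p = 0.274 and 0.142, limma), with both genes not well above background on any withdrawn array.

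Among mesoderm markers 1 gene rose and 4 fell in the run of 8 arrays, with a list adjusted p of 0.812. FOXC1 was the gene that rose, at least 4.84-fold, and TBXT, the mesoderm factor brachyury, did not pass (adjusted p = 0.141, limma) and was not well above background on any withdrawn array of that run. Neural crest markers held 1 rise, TWIST1 at least 1.28-fold (adjusted p = 0.023), and 3 falls, among them SOX10 at -1.43 (SE 0.13). Of 20 fibroblast and smooth muscle markers 4 rose and 3 fell. VIM was 4.43-fold and SPARC 2.17-fold higher, and the smooth muscle calponin CNN1 was 7.05-fold lower (adjusted p = 0.00112, 0.00859 and 0.009, limma). This list had a median of -0.45 and a mean of -0.17 while camera placed it upward, without passing (adjusted p = 0.812). Over 5 lines the adjusted p was 0.908 for mesoderm and 0.874 for both neural crest and fibroblast markers (camera), and in the mesoderm and neural crest lists the median was positive, 0.10 and 0.17, and the mean negative, -0.11 and -0.21. Adjusted over the list alone, 0 mesoderm genes, 1 neural crest gene (lower) and 7 fibroblast genes (4 higher, 3 lower) passed over 5 lines, and 6, 4 and 8 over 4 lines.

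**Figure D3:**
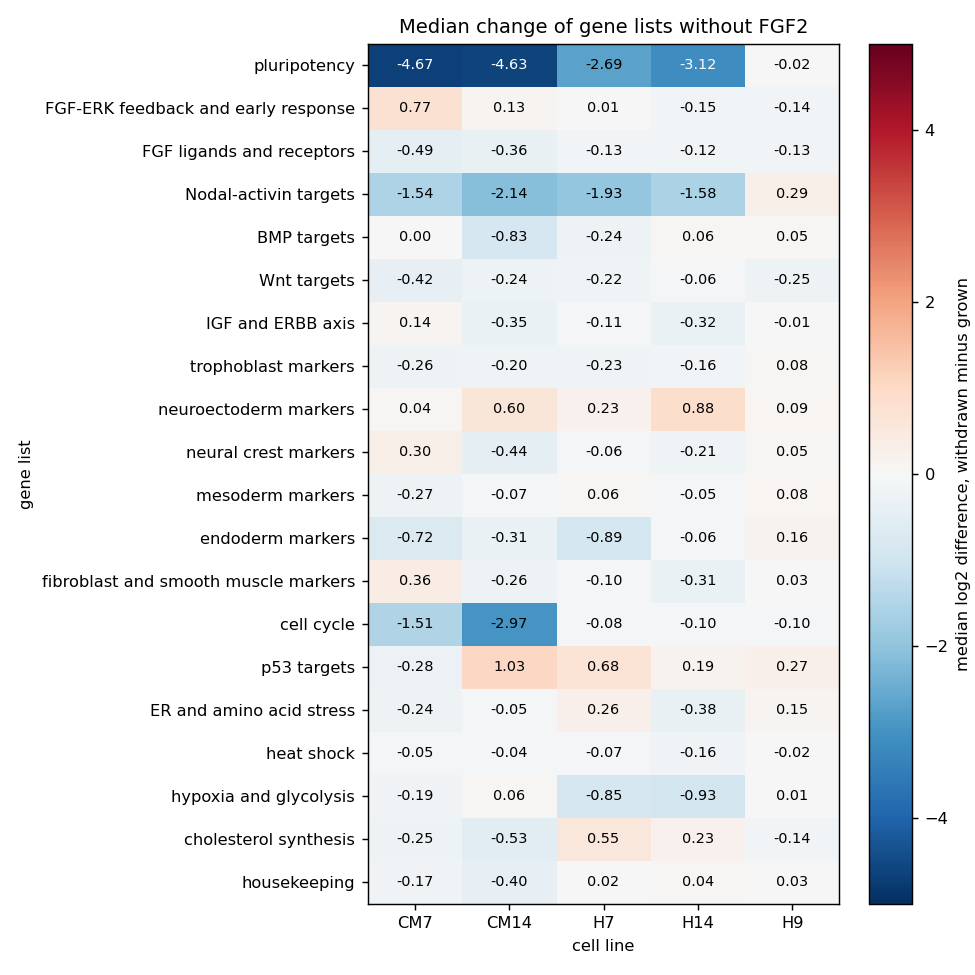
Median within-line log2 difference, without minus with FGF2, of the 20 gene lists (rows) in each of the 5 cell lines (columns), with colour giving the same value. The pluripotency median lies between -4.67 and -2.69 in CM7, CM14, H7 and H14 and at -0.02 in H9, and the cell cycle median is -2.97 in CM14 and -1.51 in CM7.

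The direct transcriptional readouts of FGF signalling through ERK did not move as a group. The list of feedback regulators and early response genes had a median of 0.15 over 5 lines (adjusted p = 0.734, camera) and a mean of -0.09, with 15 of 27 members positive. Adjusted over the list alone, 1 rose and 2 fell. DUSP6, a phosphatase that inactivates ERK, differed by 0.41 (SE 0.26, adjusted p = 0.323, limma). The feedback inhibitors SPRY4 and SPRY2 differed by -1.80 (SE 0.75) and 0.87 (SE 0.35). The ETS factors ETV4 and ETV5 differed by -2.81 (SE 0.90) and 0.33 (SE 0.79). None of these passed. ETV4 spread widely between lines, with -4.97 in CM7, -4.70 in H14 and -4.17 in CM14 against 0.15 in H7. SPRY4 lay between -4.88 in H14 and -0.13 in H7, and ETV5 between -2.62 in H14 and 2.69 in CM7. Without H9, 3 members rose and 2 fell, over all genes and over the list alone. The cyclin D1 gene CCND1 was 7.97-fold lower and the ERK phosphatase DUSP5 5.80-fold lower, while JUNB was 5.13-fold higher and the ephrin receptor EPHA2 1.94-fold higher.

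Of 29 FGF ligand and receptor genes, 8 fell and 2 rose over 5 lines when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.302, camera), though with fry it passed over 4 lines (adjusted p = 0.00019). Without H9, 6 fell and 1 rose over all genes, and 8 fell and 2 rose when adjusted over the list alone. FGF2 itself was at least 4.37-fold lower (adjusted p = 0.00282, limma) and differed by 0.21 in H9. FGFR4 was 10.7-fold lower, FGF16 at least 10.3-fold lower and FGF19 at least 2.76-fold lower. FGFR1, the main FGF receptor of these cells, differed by -0.60 (SE 0.24, adjusted p = 0.136) without passing.

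Other signalling lists did not pass camera in either set of lines. With fry, which does not compare a list with other genes, BMP targets (adjusted p = 0.0268) and Wnt targets (0.0446) passed downward over 4 lines and not over 5. BMP targets had 1 rise, ID4 at 3.12-fold, and 5 falls in the run of 8 arrays, among them ID1 at least 10.8-fold and SMAD7 at least 3.80-fold. Wnt targets held 2 falls, CCND1 and RNF43, the latter at least 1.28-fold. In the IGF and ERBB axis 4 rose and 4 fell. IGFBP5, an IGF-binding protein gene, was 20.9-fold higher and EGFR 4.64-fold higher, whereas ERBB3, a neuregulin receptor gene, was at least 19.3-fold lower. The adjusted p over 5 lines was 0.777 for BMP targets, 0.507 for Wnt targets and 0.907 for the IGF and ERBB axis (camera), whose median was -0.04 with a mean of 0.17 and an upward test. Adjusted over the list alone, 2 BMP targets and 2 Wnt targets fell over 5 lines, and 3 members of the IGF and ERBB axis rose and 4 fell. Over 4 lines 2 BMP targets rose and 5 fell, and the Wnt and IGF and ERBB lists had the counts given over all genes.

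Cell cycle genes shifted down over 5 lines, with a median of -0.96 over 24 genes (adjusted p = 0.00175, camera; adjusted p = 0.782 with an estimated correlation). The shift lay in 2 lines. The median was -2.97 in CM14 and -1.51 in CM7, against -0.10 in H14, -0.08 in H7 and -0.10 in H9. No member passed over 5 lines, whether adjusted over all genes or over the list alone. Within the run of 8 arrays AURKA and BUB1, a mitotic kinase and a spindle checkpoint kinase, fell by 1.67 (SE 0.41) and 2.15 (SE 0.56) on the log2 scale. None passed there when adjusted over the list alone. Leaving out CM14 as well ended the call of the list (adjusted p = 0.101), the highest of 17 alternatives with the preset correlation, whose lowest was 0.000248.

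The p53 target list had a median of 0.46 over 5 lines, with line medians from -0.28 in CM7 to 1.03 in CM14 and 4 of 5 positive, and did not pass (adjusted p = 0.0903, camera). It passed under 7 of 19 alternatives, in a range from 0.0268 to 0.23: without CM7 (0.0394) or H14 (0.0465), with median scaling (0.0268), cyclic loess (0.0401), dim genes left out (0.0496), and no block or a random block (0.0362 each). Over 5 lines 4 rose and 1 fell when adjusted over the list alone. Without H9, 5 of 15 rose and 1 fell, whether over all genes or over the list alone. CDKN1A, the cell cycle inhibitor p21, was 7.20-fold higher (adjusted p = 0.0307, limma), BTG2 5.83-fold and MDM2, the p53 ubiquitin ligase, 2.87-fold, while the apoptosis gene PMAIP1 was at least 11.1-fold lower. CDKN1A was higher in 5 of 5 lines, by between 0.83 in H9 and 4.96 in CM14.

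Stress and metabolic lists did not pass camera over 5 lines. With fry the heat shock list passed downward over 5 lines (adjusted p = 0.0206) and over 4 (adjusted p = 0.00104). The shift was small, with a list median of -0.17 over 5 lines and -0.04 over 4. Among hypoxia and glycolysis genes 5 of 16 fell in the run of 8 arrays, with ADM at least 11.6-fold, EGLN3 at least 3.14-fold and PGK1 at 1.90-fold. For ER and amino acid stress 2 fell, HMOX1 at least 5.27-fold and CHAC1 at 3.27-fold. For heat shock 2 fell, HSPE1 at 2.03-fold and HSPH1 at 1.73-fold. No cholesterol synthesis gene passed, and the largest of the 4 examined by rule was MSMO1 at 0.51 (SE 0.14, adjusted p = 0.0512, limma). The adjusted p over 5 lines was 0.198, 0.874, 0.433 and 0.891 in the order hypoxia, ER stress, heat shock and cholesterol synthesis (camera), and 0.834 for housekeeping genes. Of 14 housekeeping genes 1 rose and 3 fell in the run of 8 arrays. B2M, the light chain of class I molecules, was 3.35-fold higher and HPRT1 2.70-fold lower, and the list median was -0.09. Adjusted over the list alone, none of these 5 lists had a gene past the threshold over 5 lines. Over 4 lines the counts were those given over all genes, except for 2 rises among the housekeeping genes.

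The responses of the 5 lines were compared by correlating their log2 differences across the 19615 genes, which are not independent replicates. CM7 and CM14 gave r = 0.84 and H7 and H14 gave r = 0.85. Pairs of one CM line and one of H7 and H14 lay between 0.53 and 0.59. H9 lay between -0.02 and 0.11 with the other 4. The mean over the 10 pairs was 0.40 (SD 0.34), and without H9 it was 0.65 (SD 0.15) over 6 pairs. Array correlations between lines lay between 0.976 and 0.993 among FGF2-grown arrays and between 0.826 and 0.986 among withdrawn ones, where the lowest without H9 was 0.892. H7 with H14 was the exception to lower values without FGF2, at 0.982 grown and 0.986 withdrawn.

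**Figure D4:**
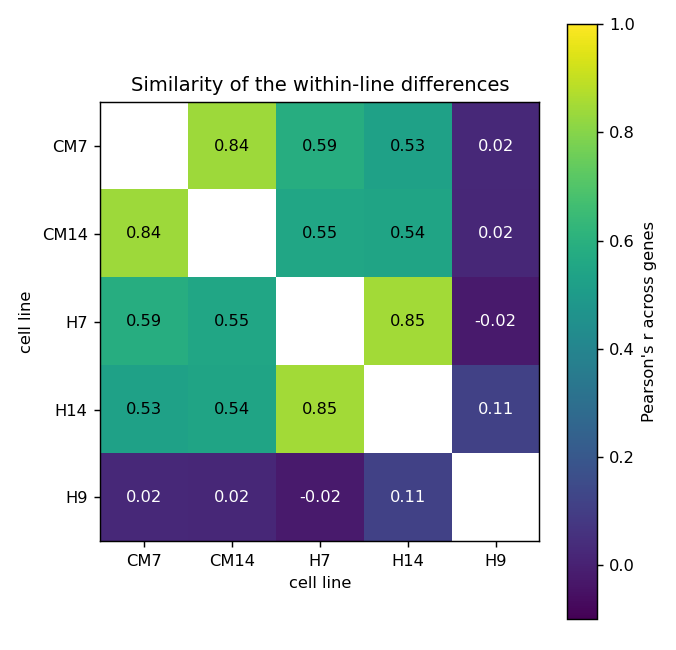
Pearson's r across 19615 genes between the log2 differences (without minus with FGF2) of each pair of the 5 cell lines. CM7 with CM14 (0.84) and H7 with H14 (0.85) are the closest pairs, and H9 lies between -0.02 and 0.11 with the other lines.

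The last comparison was between the lines themselves, over both conditions. No gene differed between the 5 lines at an adjusted p under 0.05 in limma's F test, where the smallest adjusted p was 0.135 and 835 genes had an unadjusted p under 0.05. With a trended, robust variance model 4 genes passed. Each line has 1 array per condition, so this test sets line differences against the unequal responses of the lines. The median SD of a gene between lines was 0.21 with FGF2 and 0.41 without it. Over the 4 lines other than H9 it was 0.18 and 0.30.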

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

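The test of signal compression in the H9 run, that of the background of the H14 array and both contrasts between lines were chosen after the responses of the lines had been seen.

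Over the run of 8 arrays, 1 of 32 splits that could be fitted, the real one, gave as many as 4426 genes, and the highest other split gave 222. The lines pair the arrays, and only 8 splits part every pair as the real one does, differing in which array of a line counts as grown. These are too few for a share under 0.05. The real count was 4426 and the highest other 0. Every other split, of the 32 or of the 8, leaves the FGF2 difference in its spread, which lowers its count. The low counts of the other splits therefore do not measure chance. Over 5 lines the real count was 0, which 100 of 100 splits drawn reach by definition, so the splits say nothing about chance there; the highest other count was 13.

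H9 stood apart from the other lines. Its difference was -0.57 for POU5F1, 0.67 for NANOG and 0.29 for the median of Nodal-activin targets, each farther from the nearest line than a Dixon test allows. In all, 38 of 144 named genes had H9 as such an outlier, against 0 or 1 for any other line; the named genes include those picked for agreement of the other 4 lines, and chance flags about 1 in 20 sets of values. The change in H9 differed from the mean of the other 4 lines for 266 genes (limma), where the spread comes from those 4 lines alone and the single H9 pair is assumed to vary like them. The same contrast for each other line gave 0 genes (between 211 and 1085 at an unadjusted p under 0.05), but it holds H9 in its spread and does not show that the other lines are alike. A compressed signal in the separate H9 run is argued against by the position of the H9 withdrawn array, 0.0536 of the way from the grown to the withdrawn mean of the other lines, where the grown H9 array lay at 0.0325 and the other withdrawn arrays between 0.767 and 0.992. Cells that had not reacted to the withdrawal remain open. The spread of the H9 differences, 0.42, was 0.966 of the largest spread between 2 grown arrays of different lines. Such spreads lay between 0.27 and 0.43. Because they compare different lines, they do not show how far 2 like cultures of 1 line differ, and the comparison does not decide this. A property of the H9 line, a shorter or incomplete withdrawal and an array of a culture that had kept FGF2 were not tested and stay open.

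CM7 and CM14 differed from H7 and H14 in the change of 1035 genes over the run of 8 arrays (535 higher and 500 lower in the CM lines, limma), a contrast chosen from the correlations of the responses. The other 2 ways of pairing the 4 lines gave 0 each (465 and 113 genes at an unadjusted p under 0.05), but they hold this difference in their spread and lend it no independent support. Unequal grown cultures are argued against by these genes, whose median absolute difference between the CM lines and the other 2 was 0.0793 times as large in the grown arrays as in the within-line changes. The high background of the grown H14 array is argued against too, because the H7 differences, which do not use it, correlated at most 0.586 with those of a CM line, against 0.837 between CM7 and CM14. A difference in the length of the culture without FGF2, in handling, in a property of the lines, or between the lines and the cultures that carry their names was not tested and stays open.

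In the same contrast 3 lists passed camera and none passed with an estimated correlation (adjusted p = 0.776 for each). The cell cycle list was lower in the CM lines, with a median difference in change of -2.09 over its members (adjusted p = 2.41e-12). Cholesterol synthesis was lower, at -0.64 (adjusted p = 0.00196), and hypoxia and glycolysis higher, at 0.54 (adjusted p = 0.0112).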

How the results depend on the processing

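The alternatives over the run of 8 arrays as a set of its own, those for the contrasts between lines and the similarity without H9 were chosen after the responses of the lines had been seen, and the others before. Over 5 lines the count of changed genes was 0 in the reported fit and under 8 alternatives in processing, summary, source of values or fold minimum. It was 2746 with median scaling (515 higher, 2231 lower), 949 with dim genes left out, 1069 with a trended, robust variance model, 4227 with array weights, 2767 with the line as a random block and 3464 at an adjusted p under 0.1. With no replicate block, so without the pairing, it was 2283, and within the run of 8 arrays 4426. Leaving out 1 line at a time gave between 0 and 4426, the latter without H9 only. Smallest adjusted p values lay between 0.000167 and 0.207, and beyond H9 the cause was not tested. Over 5 lines 4 lists shifted; 7 did with dim genes left out, 0 with an estimated correlation and 1, heat shock, with fry, where the cause was not tested.

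Over the run of 8 arrays the 4426 genes became between 4121 and 6289 under 15 alternatives in processing, model or threshold, of which the authors' normalized values gave 4171, sharing 3898. Leaving out a further line gave between 2194 and 2533, with 3 lines left. The 6 shifted lists became 0 with an estimated correlation and 8 with fry, of which 4 were among the 6. The neuroectoderm and cell cycle lists lost their call with fry. Median scaling moved the median of all genes to -0.20 over 5 lines and -0.27 over 4, against -0.01 in both; smaller changes are to be read relative to it. With a trended, robust model 4 genes differed between lines, 0 otherwise. The mean similarity lay between 0.398 and 0.648, and the lists with one sign in all lines numbered between 4 and 9. No named gene or list that passed reversed under these alternatives. For named genes over 5 lines, 565 values gained a call and 1499 kept their side of the threshold. None could lose a call there, since no gene passed in the reported fit over 5 lines. Over 4 lines 77 values lost their call, 45 gained one and 1726 kept their side. The contrast of the CM lines gave between 595 and 1362 genes and that of H9 between 159 and 290. Signal was lowest over background on the grown H14 array, 1.90 times the random probes, which limits calls in dim genes.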

Other observations

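The genes in the next paragraphs were chosen after their values had been seen, and the contrast behind them was added after the data had been examined.

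The genes below were picked from the extremes of the contrast of CM7 and CM14 with H7 and H14, and stand for no gene group: no list of regional, glial or progenitor genes was tested, and the neuroectoderm list did not pass in this contrast (median -0.27, adjusted p = 0.649, camera). Values are mean normalized log2 intensities on the 2 withdrawn arrays of each side, since many of these genes were near background in 1 condition. DLX1, of ventral forebrain, had 13.77 in CM7 and CM14 against 7.60 in H7 and H14 (adjusted p of the difference in change 0.00321, limma). GFAP, the astrocyte filament gene, had 15.25 against 9.14. AQP4, the astrocyte water channel, had 13.43, SLC1A2, a glial glutamate transporter gene, 13.15 and NFIA, a factor of gliogenesis, 14.45. None of these 3 was well above background on the withdrawn H7 and H14 arrays. With FGF2, NFIA was already at 10.22 in CM7 and CM14 and at 9.69 in H7 and H14. It changed by 4.23 in CM7 and CM14 and by -2.63 in H7 and H14.

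On the other side, EN2, a transcription factor of midbrain and hindbrain, had 13.39 in the withdrawn H7 and H14 arrays against 7.46 in those of CM7 and CM14, and BMP5 had 13.00 against 7.46. COL3A1, a fibrillar collagen gene, had 13.67 there. The RNA-binding protein genes LIN28B and IGF2BP1 had 12.32 and 13.32, and CRABP1, a retinoic acid-binding protein gene, 15.42 (adjusted p of the difference in change 0.00556, 0.00321 and 0.00321, limma). These 4 genes were not well above background on either withdrawn CM array. EN2, BMP5 and COL3A1 rose in H7 and H14, by 6.64, 5.13 and 6.87 on the log2 scale. LIN28B, IGF2BP1 and CRABP1 were already high there with FGF2, at 13.04, 13.57 and 14.68. They changed by -0.72, -0.25 and 0.74 in H7 and H14, and by -6.32, -7.38 and -7.48 in CM7 and CM14.

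A small set of genes moved by more than 2-fold in the same direction in all 5 lines, H9 included: 5 higher and 44 lower. Among the 49 are FOXA3, POU3F3, LHFPL6 and the 10 lower genes named by rule over 5 lines. Others were NPTX1, which encodes a neuronal pentraxin (-1.07 in H9 and between -5.23 and -4.90 in the other lines), MYH14, a nonmuscle myosin (-1.65 in H9), the lactate transporter SLC16A3 (-2.78 in H9) and the claudin CLDN4 (-1.50 in H9). None passed the test over 5 lines, and the number of such genes to be found without a shared response was not worked out. In H9, 567 genes differed by over 2-fold, 402 lower and 165 higher. Of these 190 were among the 4426 genes of the other lines, 151 lower and 39 higher in H9, and 117 lower and 73 higher in the other lines. The same direction was seen for 108 of them, as many as these numbers give without any association (108). This gives no ground to read the 49 genes as a response that H9 shares. Background was unequal in the H9 pair, with 74.1% of probes above the 95th percentile of random probes when grown and 67.6% when withdrawn. Whether this bears on the larger number of lower genes in H9 was not tested, and it limits falls in dim genes there.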
